A study of Rattus norvegicus with 6 samples.

How the data were processed

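RNA was sequenced from rat nucleus pulposus cells transduced with a Bmal1 hairpin (shBmal1, 3 libraries) or a control hairpin (shNC, 3 libraries). Per the labels' protocols, polyadenylated RNA was captured on oligo-dT beads and sequenced as paired-end reads on an Illumina NovaSeq instrument. The protocol text also carries wording on poly(A)- and poly(A)+ fractions and on adipose tissue, so how exactly it describes these libraries is uncertain. Whether both groups were prepared with the same kit and batch is not given in the sources used here. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2, with no role or order. The genome build, the annotation release, the counting program and whether strand was used are not given in the sources used here. The annotation carried by the deposited table gives Ensembl identifiers, symbols, coordinates, biotypes, and GO and KEGG terms for 32623 genes, and coordinates are printed as it gives them.

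The deposited table holds raw read counts per gene for each library, as its column names and whole-number values show. It also holds FPKM values per gene and library, computed by the authors as fragments scaled for gene length and library depth, per the file headers. Over 10394 genes with more than 20 counts in every library, the deposited FPKM was proportional to the count within a library, with an SD of at most 0.0064 on the log2 scale over genes. Genes with no count are listed by the authors at an FPKM of 1e-04. Value columns that could not be tied to a sample numbered 0.

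Groups and replicate numbers were taken from the sample titles. The design written before the data were examined allowed for a table of FPKM only or of raw counts, and the count test was used because counts were present. Genes passing filterByExpr (minimum count 10, minimum total 15) were scaled by TMM and compared between groups with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), without a replicate block, at a Benjamini-Hochberg adjusted p under 0.05. Of all genes, 14342 were tested. TMM factors were 0.936 to 0.956 in shNC and 1.05 to 1.06 in shBmal1, and the biological coefficient of variation was 0.213. CPM are TMM-scaled, means are given with the SD over 3 libraries, and log2 fold changes with their standard error. Where a group had no count, the fold is a lower bound against a floor of 3 counts over the group. This floor covers counting error alone. Bmal1 was also compared with an exact two-sided permutation test.

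Before the data were examined 27 gene lists of clock genes, matrix, signalling, stress and metabolic pathways and markers of other cell types were fixed. Of their 504 members, 490 were found by symbol. Lists with at least 3 tested members (26) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Terms of 10 to 300 tested genes were tested for enrichment with a one-sided Fisher's exact test against the tested genes carrying a term, adjusted over terms and both directions.

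Genes were named by a rule fixed beforehand. It takes Bmal1 and all tested clock list members, and the 12 largest rises and 12 largest falls among called genes with separate groups and a mean of at least 1 CPM in the higher group. Symbols with a LOC, RGD, AABR, AC, ENSRNOG, MSTRG or Rn prefix were left out of these, but the placeholder NEWGENE was not. The rule also takes up to 4 members per list with the smallest p (2 where none passed). Other list members, named because at most 5 members of their list moved in that direction, were chosen after their values were seen, as were Col1a1, Fn1, Mt-co1, Thra and the genes named in the closing observations. Some genes that these rules take are not reported here. RNA classes come from the table's biotypes, and histone and olfactory receptor genes from their symbols; these shares, and their ratios with each library left out in turn, were also computed after the data had been examined.

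The number of counts sets the precision. Total counts ran from 44043803 to 49783710 in shNC and from 8773762 to 11679587 in shBmal1, so that 3 counts correspond to between 0.0603 and 0.0681 CPM per shNC library and between 0.257 and 0.342 CPM per shBmal1 library. Changes of genes at a few CPM are therefore less certain in shBmal1, and depth and group are not separable by design. No pair of libraries within a group matched within sampling noise (chi-square per degree of freedom 11.2 to 25.2), so none was treated as a duplicate. The procedure was tested on simulated counts at these depths. For shBmal1 against shNC over 14342 genes, it called 16.4% of 67 genes changed by 0.5 on the log2 scale, 64.2% of 67 changed by 1 and 86.4% of 66 changed by 2, and 4 of 14142 unchanged genes. The simulation changed only 200 genes, in both directions, whereas 71.4% of tested genes were called in the real data. Its rates therefore do not carry over to a shift of that breadth.

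Alternatives planned before the data were examined were no filter on low counts, an FPKM minimum of 0.5 in 3 libraries, limma-trend on log2(FPKM + 1) and with pseudocounts of 0.1 and 5, quantile normalization, DESeq2 size factors, FPKM rescaled to TPM, limma without a trend, with robust fitting and with array quality weights, the DESeq2 1.42.0 Wald test, limma-voom, a 2-fold threshold, unadjusted p-values, a replicate block and each library left out in turn. FPKM alternatives tested genes with an FPKM of at least 1 in 3 libraries. Alternatives added after seeing the data were thinning of shNC counts to the mean shBmal1 total (seed 11), protein-coding genes without histone genes, removal of the 50 most abundant genes, scaling by library totals alone, and a lowess correction (span 0.3) of each library for gene length. Reads were not reanalysed, and genes sharing reads with near-identical copies or overlapping genes remain uncertain.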

Results

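RNA sequencing measured gene expression in rat nucleus pulposus cells, the cells of the gel-like core of the intervertebral disc. Per the labels, the cells came from lumbar discs of male Sprague-Dawley rats aged 4 weeks and were used at passages 3 to 5. They had been transduced for 72 hours with a lentivirus carrying a short hairpin RNA against Bmal1 (shBmal1, 3 libraries) or a negative control hairpin (shNC, 3 libraries). The total count over genes was 47626000, 49783710 and 44043803 in the 3 shNC libraries and 8773762, 11679587 and 11399166 in the 3 shBmal1 libraries. The mean was thus 4.44-fold higher in shNC (n = 3) than in shBmal1 (n = 3), and no shBmal1 library reached the depth of any shNC library. The labels do not say whether the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

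The comparison asks which transcripts differ when Bmal1 is knocked down. Bmal1 pairs with CLOCK to form the transcription factor at the centre of the circadian clock. It is listed as Arntl (ENSRNOG00000014448, protein-coding, chromosome 1, 178039063 to 178137465, forward strand; the genome build is not given in the sources used here). The Arntl transcript was lower in all 3 shBmal1 libraries. The authors' FPKM was 8.38, 9.19 and 9.90 in shNC and 0.716, 1.39 and 0.690 in shBmal1, from 1220, 1396 and 1333 counts against 20, 52 and 25. Scaled counts fell from 29.6 ± 2.14 to 2.82 ± 1.23 CPM (counts scaled to library size; SD, n = 3 per group), which left 9.55% of the control level. The log2 fold change was −3.37 ± 0.26 (SE) with an adjusted p of 1.17e-05 in edgeR's quasi-likelihood test. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow.

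Clock genes that BMAL1 is known to drive through E-box elements moved in both directions. Of 15 tested members, 6 rose, 5 fell and 4 did not pass the test. Nr1d1, which encodes the repressor REV-ERBα (ENSRNOG00000009329, chromosome 10, 86683875 to 86690815, reverse strand), rose from 52.9 ± 3.63 to 667.2 ± 47.6 CPM (log2 fold change 3.66 ± 0.09, SE; adjusted p = 4.32e-08, edgeR). Ciart, a repressor of CLOCK and BMAL1 (ENSRNOG00000042717, chromosome 2, 197987705 to 197991574, reverse strand), rose from 1.82 ± 0.52 to 279 ± 8.20 CPM (7.25 ± 0.19; adjusted p = 6.09e-08, edgeR). Cry1 and Per1, which encode components of the negative limb, rose by 2.19 and 1.53 on the log2 scale (adjusted p = 1.37e-06 and 3.98e-06, edgeR). The other 2 increases were small, at 0.35 for both Dbp and Bhlhe40. Per3 (−1.41), Usp2 (−1.92), Tef (−0.58), Tspan4 (−0.58) and Cry2 (−0.26) fell. Values of −0.14 for Per2, 0.15 for Nr1d2, −0.08 for Bhlhe41 and 0.23 for Wee1 did not pass the test. The list as a whole had a median log2 fold change of 0.15, the 77th percentile among 10000 random lists of the same size matched on mean expression, and an adjusted p of 0.0905 with the gene set test camera.

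Among 13 tested genes of the wider clock machinery, 6 rose, 3 fell and 4 did not pass. Rora, a nuclear receptor that activates Bmal1 transcription, rose from 6.17 ± 1.34 to 81.2 ± 5.92 CPM (log2 fold change 3.72). Nfil3 (2.02), Npas2, which encodes a relative of CLOCK (1.40), and Fbxl21 (1.09) also rose, as did Csnk1d, from 174 ± 4.44 to 348 ± 17.8 CPM. Besides Arntl, Csnk1e (−1.38) and Ncoa1 (−0.65) fell. Clock itself (0.24), Timeless (−0.45), Arntl2 (−1.17) and Rorb (2.80) did not pass the test. The set test gave an adjusted p of 0.563 (camera), with a median of 0.996. These clock genes moved between libraries that also differed 4.44-fold in depth and 19.3-fold in their share of mitochondrial rRNA.

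Calls of small or low-level clock changes were lost or gained when 1 library was left out or the scaling was changed. Without any 1 shNC library, Cry2 lost its call (adjusted p = 0.0678, 0.0845 and 0.0628 without replicates 1, 2 and 3, edgeR). Its shNC values were 57.9, 57.9 and 56.9 CPM, so this loss does not point to any single library. Dbp lost its call without shNC replicate 2 or 3 or shBmal1 replicate 1 or 2 (0.115, 0.112, 0.138 and 0.103). Bhlhe40 lost its call without shNC replicate 2 or 3 or shBmal1 replicate 1 (0.106, 0.106 and 0.1), and Fbxl21 without shNC replicate 3 (0.057). Per2 and Arntl2 passed without shBmal1 replicate 1 (0.044 and 0.00968), and Rorb without shNC replicate 1 (0.033). With FPKM rescaled to TPM, which sums to the same total in each library with rRNA included, Dbp and Bhlhe40 came to −0.03 and −0.03. The E-box list then had 4 members higher, 7 lower and a median of −0.23. Nr1d1 overlaps Thra on the opposite strand, and Thra, picked after its value was seen, fell by 1.61 on the log2 scale. Whether the counting used strand is not given in the sources used here.

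**Figure D1:**
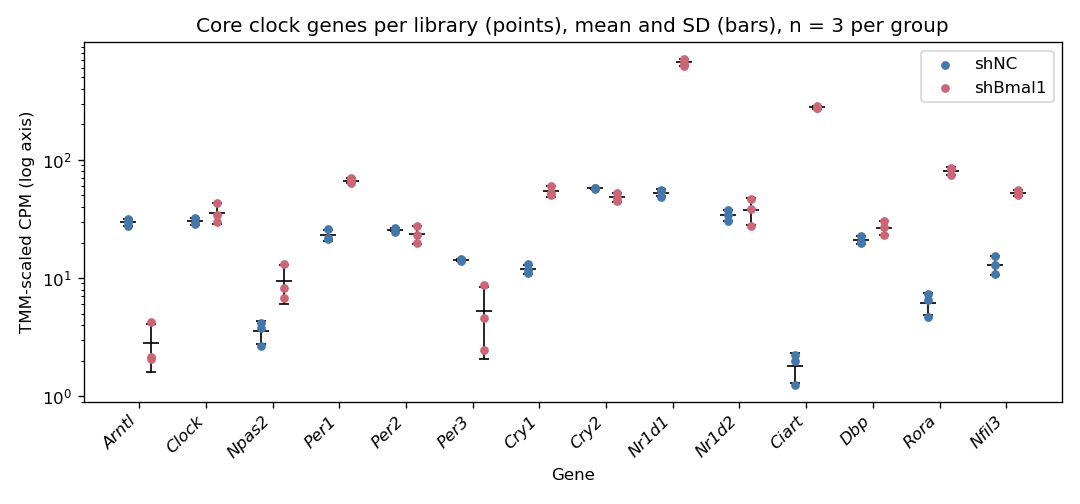
Scaled counts (CPM, log axis) of 14 clock genes, with 1 point per library and bars for the mean and SD of 3 libraries per group. Arntl lay near 29.6 CPM in shNC and 2.82 in shBmal1, while Nr1d1 and Ciart reached 667.2 and 279 CPM in shBmal1.

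Most of the transcriptome differed between the groups. Of 32623 genes listed, 12293 had no count in any library and 14342 had enough counts to be tested. At an adjusted p under 0.05 (edgeR), 10233 genes, or 71.4% of those tested, differed, with 5167 higher and 5066 lower in shBmal1. Of these, 6788 differed at least 2-fold (3647 higher, 3141 lower) and 3243 at least 4-fold (2046 higher, 1197 lower). Col1a1, the most abundant gene in shNC, fell from 7.52 ± 0.62% to 1.10 ± 0.15% of all counts, and Fn1, which encodes fibronectin, from 3.34 ± 0.15% to 2.00 ± 0.22% (SD, n = 3). The mitochondrial gene Mt-co1 was the most abundant in shBmal1, at 2.14 ± 0.07% against 1.01 ± 0.05% in shNC. The 10 most abundant genes took 21.7 to 23.1% of counts in shNC libraries and 9.05 to 9.91% in shBmal1 libraries. With FPKM rescaled to TPM, 35.6% of the calls were higher (3462 higher, 6261 lower) against 50.5% here, and the median log2 fold change of all genes was −0.43 against −0.01.

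Cartilage matrix genes were lower in shBmal1. Of 15 tested members, 9 fell, 1 rose and 5 did not pass the test. Acan, which encodes the proteoglycan aggrecan, fell from 648 ± 43.8 to 32.8 ± 4.02 CPM (log2 fold change −4.31 ± 0.11, SE; adjusted p = 5.46e-08, edgeR). Col2a1, the main collagen gene of cartilage, fell from 35.4 ± 3.91 to 0.947 ± 0.506 CPM (−5.21), Col11a1 from 11900 ± 210 to 906 ± 172 CPM (−3.71) and Fmod, which encodes fibromodulin, from 572 ± 31.7 to 88.3 ± 1.67 CPM (−2.70). The member that rose was Prg4, which encodes lubricin, from 0.148 ± 0.132 to 4.23 ± 0.38 CPM. Prg4 met the count filter through shBmal1, which largely fixed its direction. The list passed camera with an adjusted p of 0.000471, which became an adjusted p of 0.315 with an estimated correlation and 0.0708 with FPKM rescaled to TPM.

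Fibrous matrix genes were also lower, with 20 of 24 tested members falling, 2 rising and 2 not passing the test. Col3a1 fell from 11030 ± 465 to 995 ± 102 CPM (log2 fold change −3.47), Ccn2, a matricellular growth factor gene, from 10890 ± 84 to 1451 ± 101 CPM (−2.91), Sparc from 23810 ± 570 to 4451 ± 341 CPM (−2.42) and Eln, which encodes elastin, from 533 ± 81.9 to 4.80 ± 0.86 CPM (−6.81). Loxl2 (392 ± 14.7 to 966 ± 22.8 CPM) and Col6a2 (log2 fold change 0.29) rose, but Col6a2 turned to −0.49 with quantile-normalized FPKM and to −0.08 with TPM. The camera adjusted p was 9.59e-10, and the adjusted p was 0.315 with an estimated correlation. Col1a2 is listed as 2 near-identical copies on chromosome 4. The copy at 31534225 to 31569151 fell from 17130 ± 1230 to 2512 ± 250 CPM and the copy at 29529854 to 29564768 from 13480 ± 1580 to 5.98 ± 4.72 CPM, and how reads were divided between them is uncertain.

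Markers of neighbouring mesenchymal cells fell as well. Of 11 tested annulus fibrosus, tendon and fibroblast markers, 7 fell, 1 rose and 3 did not pass. Col12a1 fell by 4.79, Scx, which encodes the tendon transcription factor scleraxis, by 3.18 and Col14a1 by 2.68 on the log2 scale. Egr1, an immediate-early gene, rose by 2.13. This list gave an adjusted p of 0.0114 (camera) and of 0.315 with an estimated correlation. The camera adjusted p was 0.103 with TPM, 0.0513 with a pseudocount of 0.1 and 0.0864 without the 50 most abundant genes. Of 10 smooth muscle and myofibroblast markers, 8 fell and 2 rose. Acta2, which encodes smooth muscle actin, fell from 1649 ± 70.7 to 92.0 ± 24 CPM (log2 fold change −4.17), Tagln from 2589 ± 92.1 to 693 ± 33.5 CPM, and Lmod1 and Smtn by 3.14 and 1.77 on the log2 scale. Des (2.93) and Myh11 (0.62) rose, and Myh11 lost its call without any 1 of shNC replicates 1, 2 and 3 or without shBmal1 replicate 1 (adjusted p = 0.125, 0.0826, 0.106 and 0.118, edgeR). The camera adjusted p was 0.00142, the adjusted p was 0.437 with an estimated correlation and 0.0708 with TPM.

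Nucleus pulposus and notochord markers were split. Of 15 tested, 4 rose, 4 fell and 7 did not pass. Mgp, which encodes matrix Gla protein, fell from 1615 ± 151 to 198 ± 15.8 CPM (log2 fold change −3.03), Pax1, a sclerotome transcription factor gene, from 527 ± 12.9 to 84.9 ± 4.93 CPM (−2.63), Krt8 by 1.23 and Ncdn by 0.76. Foxf1 (0.56), Tek (3.47), Ca3 (1.35) and Slc2a1 (0.40) rose, Slc2a1 missing the threshold with TPM (adjusted p = 0.677, limma). The camera adjusted p was 0.301, with the set placed lower although its median was 0.14, and with TPM 2 of 11 tested markers were higher and 7 lower.

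TGF-beta and BMP signalling genes fell on balance, 14 of 22 tested being lower and 4 higher, with 4 not passing. Tgfb3 fell from 731 ± 43.7 to 76.9 ± 13.6 CPM (log2 fold change −3.25), Bmp4 from 473 ± 13.8 to 64.1 ± 10.5 CPM (−2.88), Tgfb2 by 2.01 and Ltbp2, which encodes a latent TGF-beta binding protein, by 1.55. Skil (46.2 ± 2.62 to 131 ± 2.74 CPM), Bambi (log2 fold change 0.78), Bmp2 (0.64) and Smad7 (0.41) rose, and SMAD7, SKI-like protein and BAMBI are known as inhibitors of the pathway. The camera adjusted p was 0.00685, and it was 0.315 with an estimated correlation, 0.0513 with a pseudocount of 0.1 and 0.0708 with TPM. With TPM, Bmp2 and Smad7 missed the threshold (adjusted p = 0.0935 and 0.777, limma). Of 19 genes of PI3K-Akt and insulin-like growth factor signalling, 12 fell, 5 rose and 2 did not pass (camera adjusted p = 0.102, and 0.0363 without a filter). Akt1 fell from 300.2 ± 1.53 to 122 ± 11.2 CPM, Irs1 by 1.71, Igfbp4 by 3.03 and Pik3r1 by 0.98 on the log2 scale. Among those that rose were Foxo3 (0.96), Pik3cb (0.69) and Irs2 (0.58), of which Pik3cb and Irs2 missed the threshold with TPM (adjusted p = 0.188 and 0.206, limma).

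Inflammatory and NF-kB genes were higher in shBmal1. Of 21 tested, 14 rose, 1 fell and 6 did not pass. Cxcl1, a neutrophil chemokine gene, rose from 4.47 ± 0.44 to 181 ± 14.6 CPM (log2 fold change 5.34 ± 0.11, SE; adjusted p = 3.68e-08, edgeR). Ptgs2, which encodes cyclooxygenase-2, rose from 51.9 ± 2.78 to 622 ± 35.9 CPM (3.58), Tnfaip3, a feedback inhibitor of NF-kB, from 3.69 ± 0.26 to 82.6 ± 6.59 CPM (4.48) and the NF-kB subunit gene Relb by 3.16 on the log2 scale. Icam1, an adhesion molecule gene, was the member that fell, from 364 ± 1.57 to 168 ± 7.30 CPM. The camera adjusted p was 0.000185, and the adjusted p was 0.315 with an estimated correlation.

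Of 20 tested interferon-stimulated genes, 13 rose, 2 fell and 5 did not pass (camera adjusted p = 0.103, and 0.0409 with a replicate block). Rsad2 went from 1 count over the shNC libraries to 770 over the shBmal1 libraries and Oasl from 4 counts to 814. Both genes met the count filter through shBmal1, so the filter largely fixed their direction. Stat2 rose from 42.2 ± 0.38 to 154 ± 16.7 CPM, while Ifit2 fell from 36.0 ± 2.10 to 10.2 ± 1.91 CPM. Matrix proteases and their inhibitors moved both ways, with 9 of 18 tested genes higher, 8 lower and 1 not passing (camera adjusted p = 0.505). Mmp3, which encodes stromelysin-1, rose from 3.52 ± 0.14 to 66.9 ± 6.20 CPM (log2 fold change 4.25), Plaur, the urokinase receptor gene, from 8.40 ± 0.17 to 415 ± 52.1 CPM (5.62) and Timp1 from 95.1 ± 3.94 to 290 ± 17.8 CPM (1.61). Mmp14, which encodes a membrane-bound collagenase, fell from 422 ± 22.7 to 116 ± 8.15 CPM (−1.86).

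Targets of p53 were mostly higher. Of 19 tested genes of the p53 and senescence list, 13 rose, 5 fell and 1 did not pass. Aen, a nuclease gene, rose from 50.0 ± 2.75 to 1007 ± 19.8 CPM (log2 fold change 4.33), Ccng1, which encodes cyclin G1, from 183 ± 6.07 to 1529 ± 116 CPM (3.06), Gadd45a from 91.5 ± 2.00 to 626 ± 27.1 CPM (2.77) and Cdkn1a, which encodes the cell cycle inhibitor p21, from 264 ± 8.85 to 1726 ± 115 CPM (2.71). Fas (−2.86), Cdkn2b (−1.86), Lmnb1 (−1.12), Cdkn2a (−0.87) and Glb1 (−0.69) fell; Cdkn2a and Cdkn2b encode the cell cycle inhibitors commonly read as senescence markers, and Lmnb1 a lamin. The camera adjusted p was 3.47e-07, and the adjusted p was 0.315 with an estimated correlation. The matrix, signalling, inflammatory and p53 groups all moved between libraries whose depth differed 4.44-fold and whose mitochondrial rRNA share differed 19.3-fold.

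Cell cycle genes moved both ways, with 14 of 34 tested genes higher, 12 lower and 8 not passing (camera adjusted p = 0.795). Bub1 (2.50), Mcm7 (2.42) and Aurka (1.96) rose, and Cdk1, the mitotic kinase gene, fell from 20.5 ± 3.25 to 1.59 ± 0.45 CPM. With TPM, 10 were higher and 16 lower. Among 18 apoptosis genes, 6 rose, 7 fell and 5 did not pass (camera adjusted p = 0.79), and with TPM 3 were higher and 10 lower. Birc3 (1.52) and Bcl2l11, which encodes the pro-apoptotic protein BIM (1.34), rose, and Bnip3 (−1.08) and Bad (−0.99) fell.

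Genes of the hypoxia response and glycolysis were lower in 14 and higher in 5 of 26 tested, with 7 not passing (camera adjusted p = 0.0905). The list passed without a filter (adjusted p = 0.0165), with quantile-normalized FPKM (0.0194) and without shBmal1 replicate 1 (0.043). Ca9, a carbonic anhydrase gene induced by hypoxia, fell from 702 ± 15.1 to 178 ± 17.2 CPM, and the collagen prolyl hydroxylase genes P4ha1 and P4ha2 fell by 1.35 and 1.65 on the log2 scale. Hk2 (1.34), Slc2a3 (0.93), Vegfa (0.86), Eno1 (0.30) and Egln3 (3.76) rose. Eno1 turned to −0.44 with quantile-normalized FPKM and to −0.07 with TPM, and Egln3 lost its call without shNC replicate 3 (adjusted p = 0.0587, edgeR). Egln3, at 0.166 ± 0.211 CPM in shNC, met the count filter through shBmal1, which largely fixed its direction.

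Of 23 oxidative phosphorylation genes, 10 rose, 6 fell and 7 did not pass (camera adjusted p = 0.563), and with TPM 6 were higher and 12 lower. The cytochrome oxidase subunit genes Cox6c (1.63), Cox4i1 (1.15) and Cox5b (0.91) rose and Sdha (−0.65) fell. After a correction for gene length Cox5b came to 0.01 and was not called. Of 18 antioxidant genes, 9 rose, 7 fell and 2 did not pass (camera adjusted p = 0.951, the set placed lower although its median was 0.14), and with TPM 4 were higher and 10 lower. Hmox1, which encodes heme oxygenase 1, rose from 130 ± 6.07 to 1200 ± 262 CPM and the cystine transporter gene Slc7a11 by 1.35 on the log2 scale. Sod3 (−1.28) fell.

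Of 21 autophagy and lysosome genes, 12 rose, 4 fell and 5 did not pass (camera adjusted p = 0.0905, and 0.0431 among protein-coding genes without histone genes), and with TPM 10 were higher and 8 lower. Gabarapl1 (2.15), Gabarap (1.76), Sqstm1, which encodes the autophagy receptor p62 (1.41), and Ctsl (1.22) rose. Tfeb, a lysosomal master regulator gene (−2.56), Wipi1 (−1.94), Atg9a (−1.39) and Ulk1 (−1.13) fell. Of 17 genes of the unfolded protein response, 9 rose, 7 fell and 1 did not pass (camera adjusted p = 0.144), and with TPM 6 were higher and 8 lower. Atf3 (5.43), Dnajb9 (3.13) and Ddit3, which encodes CHOP (2.04), rose and Pdia6 (−1.69) fell. Of 19 cholesterol synthesis genes, 6 rose, 9 fell and 4 did not pass (camera adjusted p = 0.79), and with TPM 4 were higher and 10 lower. Msmo1 (2.07) and Sc5d (0.98) rose, and Lss (−1.92) and Srebf2, which encodes a regulator of the pathway (−1.46), fell.

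**Figure D2:**
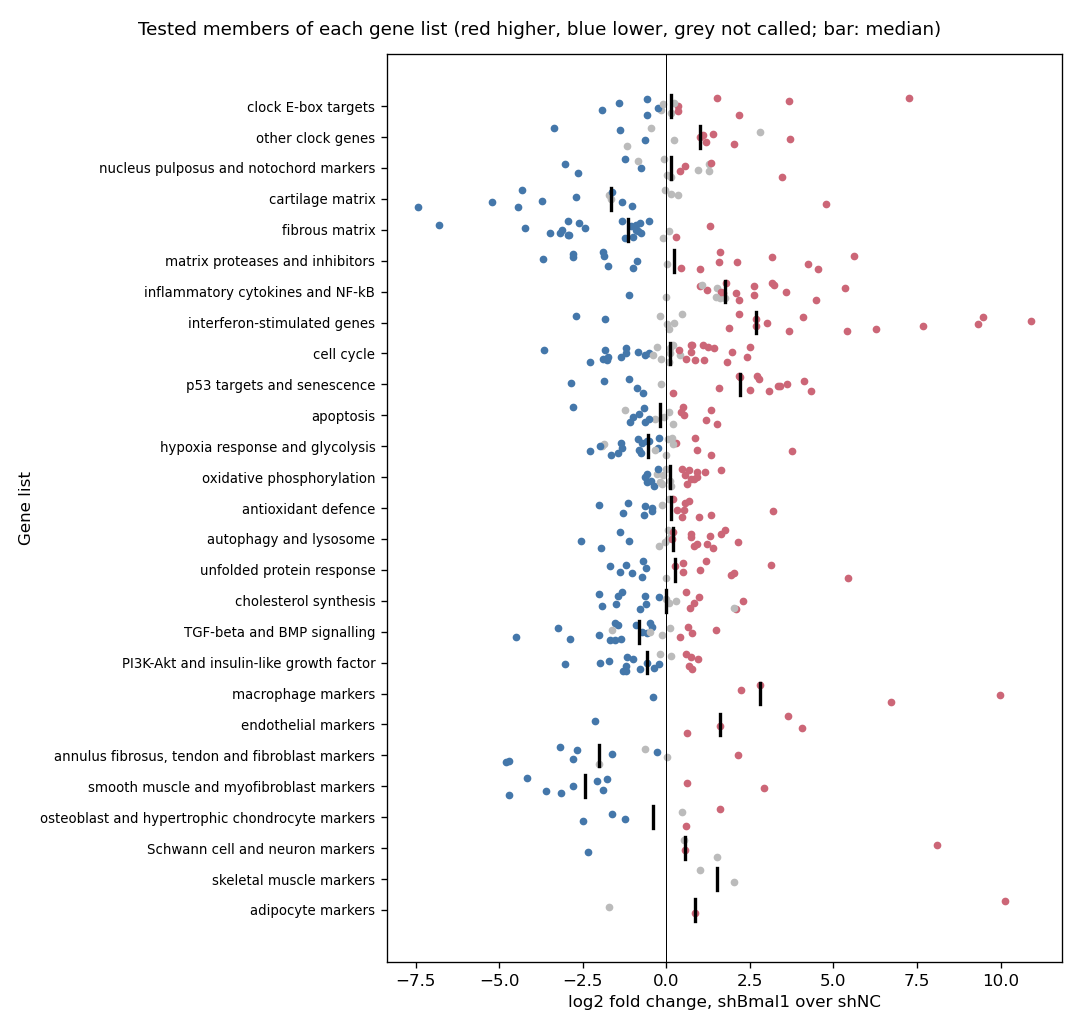
Log2 fold change (shBmal1 over shNC) of every tested member of the 27 gene lists, with 1 point per gene, red for called higher, blue for called lower, grey for not called, and a bar at the list's median. Epyc, Mx2, Mrc1, Sox10 and Adipoq had no count in 1 group and are drawn at a fitted value that depends on the prior count. The fibrous matrix list lay mostly below 0 (median −1.14) and the p53 list mostly above (median 2.22).

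Markers of other cell types moved both ways. Of 12 macrophage markers listed, 5 were tested, of which 4 rose and 1 fell (camera adjusted p = 0.414). Mrc1 had no count in shNC and 156 in shBmal1, at least 199-fold higher, and Fcer1g (6.72), Cd68 (2.81) and Lyz2 (2.25) rose from levels under 1 CPM to between 2.75 and 10.8 CPM. Cd14 (−0.40) fell. Of 10 endothelial markers listed, 5 were tested, of which 4 rose and 1 fell (camera adjusted p = 0.79). Vwf (4.06), Tie1 (3.63), Flt1 (1.61) and Egfl7 (0.61) rose and Esam (−2.13) fell. With TPM, 2 endothelial markers could be tested and 0 were called higher. Of 6 osteoblast and hypertrophic chondrocyte markers, 2 rose, 3 fell and 1 did not pass (camera adjusted p = 0.736). Spp1, which encodes osteopontin (0.59), and Ibsp (1.62) rose, and Runx2 (−1.24), Phex (−1.61) and Alpl (−2.48) fell. Of 5 Schwann cell and neuron markers, 2 rose, 1 fell and 2 did not pass (camera adjusted p = 0.951, the set placed lower although its median was 0.57). Sox10 had no count in shNC and 41 in shBmal1, at least 54.6-fold higher, Tubb3 (0.57) rose, and S100b, also a nucleus pulposus and chondrocyte transcript, fell from 41.6 ± 1.96 to 8.21 ± 1.63 CPM. Of 3 adipocyte markers, 2 rose (camera adjusted p = 0.597). Adipoq had no count in shNC and 172 in shBmal1, at least 224-fold higher, and Pparg (0.86) rose. Of the skeletal muscle markers, 2 were tested, Tnnt3 (2.02) and Acta1 (1.01), and neither passed. Mrc1, Fcer1g, Vwf, Tie1, Sox10 and Adipoq had means of at most 0.133 CPM in shNC and met the count filter through the shBmal1 libraries. The filter thus largely fixed that they were called higher.

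Several of these marker calls were lost when 1 library was left out, some of them whichever of several libraries it was. Tubb3 lost its call without shNC replicates 1, 2 or 3 or shBmal1 replicates 2 or 3 (adjusted p = 0.0558, 0.12, 0.0965, 0.0572 and 0.0795, edgeR), and Pparg without shNC replicates 1, 2 or 3 or shBmal1 replicate 2 (0.0534, 0.0538, 0.0789 and 0.0913). Flt1 lost its call without shNC replicates 1 or 2 or shBmal1 replicates 1 or 3 (0.0898, 0.11, 0.0836 and 0.118), and Lyz2 without shNC replicates 1 or 2 or shBmal1 replicate 1 (0.0524, 0.0538 and 0.0513). Alpl did so without shNC replicates 2 or 3 (0.0751 and 0.0957), Cd14 without shNC replicate 3 or shBmal1 replicate 2 (0.156 and 0.0873), Ibsp without replicate 1 of either group (0.0557 for shNC, 0.0561 for shBmal1) and Tie1 without shBmal1 replicate 1 (0.0514). Without shBmal1 replicate 1, Tnnt3 and Acta1 passed (8.31e-05 and 8.95e-05). Spp1 turned to −0.11 with quantile-normalized FPKM.

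With p-values adjusted over the list alone, the count of higher and lower genes became 16 and 1 in the inflammatory list, 5 and 15 in the hypoxia list and 1 and 8 in the annulus fibrosus list, and stayed as given in every other list. With camera's preset correlation 7 of the 26 lists with at least 3 tested members passed, with an estimated correlation 0 did (3 at an unadjusted p under 0.05), and the directional test fry, which does not compare a list with other genes, called 21. In every gene named as rising or falling except Flt1, the 3 libraries of 1 group all lay above the 3 of the other, which chance gives for 10% of genes.

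Of the 12 increases named by a rule of size, all but Gltpd2 were in genes with no count in shNC. Apoa2, an apolipoprotein gene (chromosome 13), had 4110 counts in shBmal1 and was at least 5470-fold higher. The bounds were 4240-fold for Bpifb1, 2790-fold for Clpsl2, 1690-fold for Mip, the lens aquaporin gene, 1020-fold for Tmem200c, 993-fold for Prl7a3, 908-fold for Sycp2, a meiotic chromosome gene, 874-fold for Tmco5b, 703-fold for Sall3 and Cpne7 and 656-fold for Srcin1. Gltpd2 rose from 1.09 ± 0.58 to 4058 ± 467 CPM (chromosome 10, 57125961 to 57128686). In all, 497 genes called higher had no count in any shNC library. Such a gene met the count filter through shBmal1 alone, so higher was the only direction in which it could be called.

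Of the 12 decreases named by the same rule, all but a copy of Col1a2 were in genes with no count in shBmal1. Aspnl1 fell from 24.9 ± 0.66 CPM and was at least 279-fold lower, and Lnx1, a ubiquitin ligase gene, at least 143-fold. Bounds for the others were 93.1-fold for Dcun1d2, 62.7-fold for Wscd2, 51.7-fold for Rnf144a, 51.4-fold for Nrip2, 48.6-fold for Apcdd1, a Wnt inhibitor gene, 47.4-fold for Pyroxd2, 46.1-fold for RragB, 45.7-fold for Odf3l1 and 43.3-fold for Kifc2. The Col1a2 copy is the NEWGENE_621351 entry described above. In all, 126 genes called lower had no count in any shBmal1 library, and the lower depth there widens the bound that a count of 0 allows. These genes met the count filter through shNC alone and could only be called lower.

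Annotation terms carried by the files were tested in both directions, and 245 of 6816 tests passed (116 in genes called higher, 129 in genes called lower). Among higher genes the pathway Ribosome led, with 119 of 161 tested genes called higher where 60 were expected (Fisher's exact test, adjusted p = 5.82e-18), followed by mRNA processing (144 of 216, 75.8 expected, adjusted p = 5.82e-18) and rRNA processing (77 of 96, 33.7 expected, adjusted p = 2.7e-16). The term olfactory receptor activity also passed, but its 32 tested genes met the count filter through the shBmal1 libraries (0 reached its level in every shNC library and 28 had no shNC count), so the filter largely fixed that all 32 were called higher. Among lower genes the leading terms were actin cytoskeleton organization (92 of 149, 55.7 expected, adjusted p = 3.85e-07), extracellular matrix (99 of 165, 61.6 expected, adjusted p = 7.75e-07), actin binding (136 of 248, 92.6 expected, adjusted p = 3.69e-06) and focal adhesion (86 of 142, 53 expected, adjusted p = 4.2e-06). With genes at least 2-fold changed, 126 tests passed. Fisher's exact test treats the genes of a term as independent, so genes that move together can make its p-values too small. Terms were not retested with TPM, quantile normalization or length correction.

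The libraries also differed in RNA composition. Mitochondrial rRNA took 0.0476 ± 0.0137% of counts in shNC and 0.919 ± 0.339% in shBmal1 (SD, n = 3), 19.3-fold more, and nuclear rRNA 0.0107 ± 0.0067% against 0.212 ± 0.143%. Small nuclear RNA took 0.00124 ± 0.000339% against 0.0235 ± 0.0154% (19.1-fold), and the class holding 7SK, Y and signal recognition particle RNA 0.0101 ± 0.00847% against 0.305 ± 0.182% (30.1-fold). Without shBmal1 replicate 1 these were 11.9-fold and 19.7-fold, and nuclear rRNA went from 19.8-fold to 12.3-fold; without shNC replicate 2 the 7SK class was 54.1-fold higher. The share of small nucleolar RNA was 4.86-fold higher, of pseudogenes 2.53-fold, of long intergenic RNA 2.16-fold, of histone cluster genes 4.59-fold and of olfactory receptor genes 11.1-fold. The 13 mitochondrial protein-coding genes together took 2.69 ± 0.14% and 3.52 ± 0.09%, with Mt-co1 higher and 11 of the 13 lower in shBmal1 (edgeR). With library totals alone as scaling, 6 were lower. Each of these shares separated the 3 libraries of 1 group from those of the other, with an exact two-sided permutation p of 0.1, the smallest possible. Correlations of log2(FPKM + 1) across 12464 genes, which are not independent replicates, were 0.986 to 0.988 within shNC, 0.966 to 0.974 within shBmal1 and 0.731 to 0.748 between the groups. The first principal component, which separated the groups, held 88.9% of the variance.

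**Figure D3:**
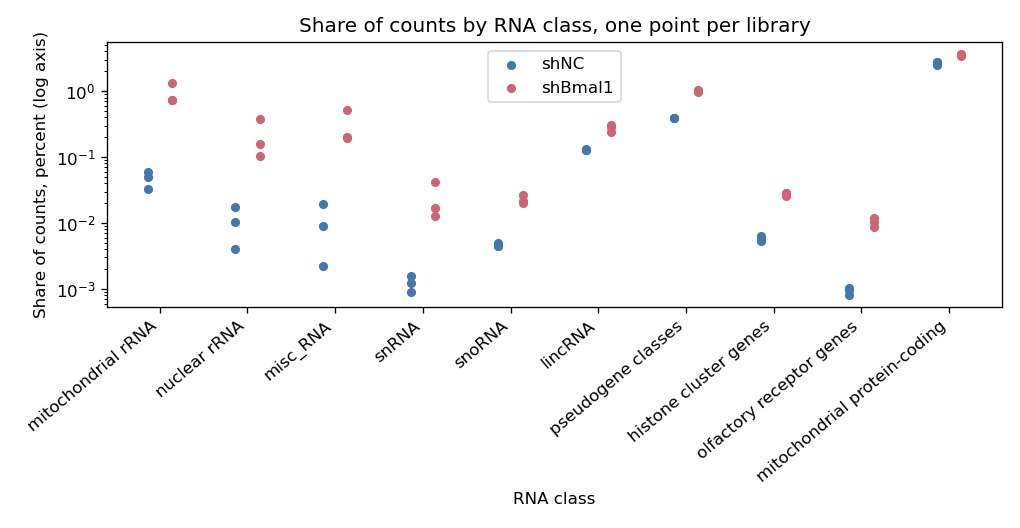
Share of all counts in percent (log axis) by RNA class, with 1 point per library. In every class shown the 3 shBmal1 libraries lay above the 3 shNC libraries, from 1.31-fold on average for mitochondrial protein-coding genes to 30.1-fold for the misc_RNA class (19.7-fold without shBmal1 replicate 1 and 54.1-fold without shNC replicate 2).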

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

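Thinning, protein-coding genes, removal of abundant genes, library totals and length correction were chosen after the data had been seen. The count of 10233 genes stayed within 1.5 times under every other model, filter and scaling, and fell to 6788 (3141 lower) with a 2-fold threshold. Without 1 library it ranged from 9274 to 10617 (4809 to 5237 higher, 4459 to 5380 lower), Bmal1 from −3.84 to −3.21, lists passing from 7 to 8 and terms from 204 to 265. The replicate numbers showed no sign of pairing the samples, though pairing cannot be excluded. Correlations of deviations were −0.0455, 0.0191 and 0.0681 for equal numbers and −0.109 to 0.0791 for other pairs. A replicate block gave 9415 genes. Lists passing numbered 3 with TPM, 0 with an estimated correlation (camera in limma; 3 at an unadjusted p under 0.05) and 21 with fry. Terms fell to 126 with 2-fold genes, and the highest correlation between groups from 0.748 to 0.732 over genes with FPKM of at least 10 in all libraries. The median log2 fold change of all genes shifted to −0.43 with TPM, −0.11 with quantile normalization, 0.15 with library totals and 0.31 without a filter, and of the 10233 genes 9, 44 and 31 were called in the opposite direction with TPM, quantile normalization and length correction.

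Of 4689 values of named genes under alternatives, 4568 kept direction and side of the threshold, 90 lost the call, 10 gained it and 21 changed sign. The cause was not tested. Sign changes of log2 fold changes were, for Bhlhe41, 0.023 on the log2(FPKM + 1) scale (with, without trend, and robust), 0.025 and 0.017 with pseudocounts 0.1 and 5, 0.13 thinned and 0.077 with library totals; for Per2, 0.0019 with quantile normalization, 0.017 with library totals and 0.075 with length correction; with quantile normalization Spp1 −0.11, Col6a2 −0.49 and Eno1 −0.44; with TPM Nr1d2 −0.23, Dbp −0.025, Bhlhe40 −0.031, Wee1 −0.14, Clock −0.13, Col6a2 −0.084 and Eno1 −0.075. Without 1 library Nr1d2 ranged from −0.072 to 0.30. Of 623 list values, 570 kept direction and side, 14 lost the call, 20 gained it and 19 changed direction, with adjusted p-values for antioxidant defence of 0.775 (log2(FPKM + 1) models), 0.792, 0.76 (pseudocounts 0.1 and 5), 0.826 (replicate block), 0.817 (without shBmal1 replicate 1; direction held at 0.826 to 0.991 without any other library), 0.986 (thinned), 0.946 (protein-coding), 0.898 (library totals) and 0.482 (fry); apoptosis 0.994, oxidative phosphorylation 0.76 and unfolded protein response 0.763 (quantile); oxidative phosphorylation and cholesterol synthesis 0.964 (length); and Schwann cell markers 0.791 (replicate block) and 0.299 (fry). TGF-beta and annulus fibrosus lists lost their calls with a pseudocount of 0.1 (0.0513), and the interferon list passed with the replicate block (0.0409). Depth limits low genes most in shBmal1, where 3 counts are up to 0.342 CPM.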

Other observations

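The groups described first, the RNA preparation, genomic DNA, overlap and scaling tests were chosen after the results were seen, and the depth, gene length and upstream transcription tests were added after the data were seen but before their own results.

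Stress-response genes were among the most abundant increases. Of 17 tested heat shock genes, 15 rose and 0 fell (edgeR; median log2 fold change 2.09), with 1 called lower under quantile normalization and TPM. Hsph1, a chaperone gene, rose from 59.1 ± 2.05 to 2542 ± 200 CPM (SD, n = 3 per group) and Hspa1b, the inducible HSP70 gene, from 92.0 ± 5.67 to 4644 ± 777 CPM, although its near-identical gene copies leave its level uncertain. Of 23 immediate-early genes, 18 rose and 4 fell (median 1.78); Jun rose from 54.9 ± 1.07 to 1128 ± 112 CPM and Plk2 from 40.9 ± 2.55 to 2172 ± 318 CPM. Of 36 proteasome subunit genes, 26 rose and 0 fell (median 0.83), with 3 and 4 called lower under quantile normalization and TPM.

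Ribosomal protein genes rose in 73 and fell in 3 of 81 tested (median 1.27; 60 to 76 higher over 4 other scalings), Rplp0 going from 1721 ± 51.9 to 4763 ± 319 CPM. Of the 13 mitochondrially encoded protein genes, 11 fell (6 to 12 over 4 other scalings) and 1, Mt-co1, rose (median −0.38). Creg1, a secreted glycoprotein gene, went from 1.64 ± 0.26 to 4204 ± 144 CPM and Khk, the ketohexokinase gene, from 2.27 ± 1.41 to 1668 ± 513 CPM. Histone cluster genes, whose transcripts mostly lack a poly(A) tail, rose in 15 of 17 tested and fell in 0 (edgeR; 1.66 to 4.99 as median over 4 other scalings).

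The first pattern is that 71.4% of tested genes differed. With shNC counts thinned to the shBmal1 mean the number of calls was 92.8% of the original, and after length correction 98.5%. These totals include newly called genes. Of the 10233 genes, 9294 and 9480 were called again in the same direction, and 0 and 31 in the opposite one. These values argue against depth or gene length bias as the whole cause. Mitochondrial rRNA was 19.3-fold higher in shBmal1, so a difference in RNA preparation between the groups may contribute; protein-coding genes without histone genes gave 9613 calls (93.9%), but as they are 13346 of the 14342 tested genes their number settles nothing, and because preparation would follow the group it cannot be told apart from the knockdown. The real split was 1 of 10 splits with that many calls (10233 genes, highest other 0 in edgeR, with 14 to 47 genes at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Every other split also mixed shNC and shBmal1 libraries on each side, which turned the group difference into spread. Its low count was thus largely fixed in advance, and no conclusion is drawn from the splits. The hairpin's effect on the cells stays open alongside preparation.

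The second pattern is the 497 genes called higher without any shNC count, a direction that the count filter fixed. Genomic DNA covering the genome evenly in the shBmal1 libraries would reach silent genes too. At the median density of these genes, about 34.6 counts would be expected for each olfactory receptor gene. Of 1131 olfactory receptor genes, 78.2% had no count in any shBmal1 library, which argues against even coverage at that density. The density comes from genes that met the count filter through shBmal1, so the comparison cannot judge sparser or uneven coverage. A low level of genomic DNA stays open, since 247 olfactory receptor genes had a count in shBmal1 against 12 in shNC. Of the 497 genes, 20 are olfactory receptor genes by symbol and 28 by annotation term. A same-strand active gene ended within 10 kb upstream of 5.43% of the protein-coding genes among them (22 of 405). Among other protein-coding genes silent in shNC the share was 2.37% (167 of 7059, odds ratio 2.37, 95% interval 1.43 to 3.76, Fisher's exact p = 0.000826). Those other genes did not need counts in shBmal1, whereas the called genes did. The excess therefore cannot tell transcription running on from an upstream gene from expression near active genes, and no conclusion is drawn. At 22 of 405, running on would in any case cover few of these genes. Most are left without an explanation tested here, and a biological response to the hairpin stays open.

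The third pattern is that Nr1d1, Ciart, Cry1 and Per1, which BMAL1 is known to activate, were higher while Bmal1 was lower; they are the members with the largest rises among 15 tested E-box targets, of which Per3, Usp2, Tef, Tspan4 and Cry2 fell. Of these 4 genes, 0 overlap a gene called higher: Ciart, Cry1 and Per1 overlap no annotated gene, and Nr1d1 overlaps Thra, which fell. This argues against reads of annotated overlapping genes only. Unannotated transcripts and transcription running past the end of a nearby gene were not examined for them. Their lowest log2 fold change over 6 other scalings was 1.11, so each of the 4 stayed higher under the scalings tried. They were picked for large rises, and the median of all genes moved no further than to −0.43 (TPM). A change of sign was therefore hardly possible, and no conclusion on scaling is drawn. The list as a whole moved both ways in the main test, with 6 members higher and 5 lower. With TPM 4 were higher and 7 lower (median −0.23), Dbp and Bhlhe40 changing sign. Other candidate explanations that remain untested are a stress response acting on these promoters, a difference in clock phase at harvest, since no collection time is given in the sources used here, and the RNA preparation difference above.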
